A study of Homo sapiens with 18 samples.

How the data were processed

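RNA immunoprecipitation sequencing (RIP-seq) was carried out in U373-MG cells, an established human glioblastoma line. Per the labels, cells were transduced with an empty vector (control), with FLAG-tagged wild-type ADAR3 (ADAR3 WT) or with an ADAR3 carrying a mutated R-domain (R-mutant). Per the labels' protocols, cells were crosslinked with UV light at 150 mJ/cm2 before lysis and immunoprecipitation, ribosomal RNA was depleted, and strand-specific libraries were amplified for 15 PCR cycles. Input libraries started from 1 ug of total RNA, and each IP library used all of the precipitated RNA, per the same protocols. The molecule label reads polyA RNA, while the protocol names ribosomal RNA depletion. The 18 libraries fall into 6 groups of 3 replicates, from 3 genotypes and 2 fractions (input and IP). The labels number the replicates but do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

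The submitters' processing notes name STAR 2.7.7a, featureCounts, DESeq2 and the GRCh38 build. The gene annotation, the DESeq2 version, the model formula and the libraries in each model are not given in the sources used here. The analysis started from 4 deposited comparison tables keyed by Ensembl gene ID. A set of 3 tables compares IP enrichment between genotypes (ADAR3 WT over control, R-mutant over control, R-mutant over ADAR3 WT), and the other compares input RNA between ADAR3 WT and control. Per the file headers, each table gives a mean signal, which is the mean of normalized counts over the libraries of the authors' model. Per the file headers, each also gives a log2 fold change with its standard error on the log2 scale. The deposited test statistic is a score with no fixed range. The deposited p-values come from that statistic, with an adjusted p-value that is absent for genes of low mean. Total counts per library were not analysed here, so the sequencing depth of each library is unknown, and the deposited mean and standard error stand in for precision. The input table also holds 6 per-library columns whose names match no label, and these were not used.

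The deposited statistic was checked against its p-value before any test was run. In the 3 IP tables, the p-values of the authors' likelihood ratio test match a chi-square distribution with 7 degrees of freedom. The relative tolerance was 0.001, and only IDs with a positive statistic and a p-value away from the extremes were compared. The statistic was below 0 for 2802 IDs in ADAR3 WT over control, 1932 in R-mutant over control and 2132 in R-mutant over ADAR3 WT. A chi-square distribution does not give such values, and their cause was not examined. The test therefore covers more terms than the single log2 fold change printed beside it. In the input table, the authors' statistic equals the log2 fold change over its standard error. The design written before the data were examined took the authors' adjusted p-value at 0.05, split by the sign of the fold change. That choice was changed after the data, including the counts of genes under both tests, had been seen. The test used for all 4 comparisons was a two-sided normal test of the deposited log2 fold change over its deposited standard error. Benjamini-Hochberg adjustment at 0.05 ran over the genes that have a deposited adjusted p-value, which were 21121, 21120, 23385 and 20411 genes. Counts under the authors' adjusted p-value are given beside it.

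The fold changes in the IP tables were read as the ratio of IP over input in the first genotype to that in the second. This reading is not stated in the labels. It rests on the tables' names and on a dependence on input noise. Among genes with an input mean under 10, the fold change of ADAR3 WT over control had a slope of -0.69 on the input fold change of ADAR3 WT over control. The corresponding slope for R-mutant over ADAR3 WT was 0.46. These are the signs that shared input libraries give when input stands in the denominator.

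Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The procedure was tested on simulated data, with 200 genes changed by a known amount and errors drawn from the deposited standard errors. At a log2 change of 1, 31.5% of changed genes were recovered for ADAR3 WT over control (21121 genes) and 24.5% for R-mutant over control (21120 genes). The shares were 39.5% for R-mutant over ADAR3 WT (23385 genes) and 42.0% for the input (20411 genes). At a log2 change of 2 the shares were 72.0%, 61.0%, 64.0% and 82.5% in the same order. Among changed genes with a mean of at least 50, the shares at a log2 change of 1 were 51.2%, 37.7%, 66.4% and 64.1%. The largest number of false calls was 11 of 133 calls, for R-mutant over control at a log2 change of 2. These shares hold for 200 changed genes and for errors as wide as the deposited standard errors. With more genes changed, the adjusted threshold would be less strict and the shares higher. Because ADAR3 WT and R-mutant share the control libraries, 100 simulations without any effect gave the correlation and covariance that shared controls produce. The variance of each genotype was solved from the standard errors of the 3 IP tables, and negative solutions were taken as no variance. Errors were drawn independently for each gene. Correlations across genes are descriptive, since genes are not independent replicates. Intervals on medians and slopes came from 1000 resamples of genes and ignore dependence between genes.

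The rule set before the data were examined named the 8 genes with the largest rise and fall per comparison among genes with a symbol, an adjusted p under 0.05 and a mean of at least 50, plus members of gene lists. The rule could not be followed, because the tables do not pair IDs with symbols and 0 of 60666 IDs matched the reference table. The 2 highest and 2 lowest called IDs with a mean of at least 50 are given per comparison in its place. No ID was assigned to the transduced gene, which may be among the IDs printed, so its level was not used to check the labels. The 23 gene lists fixed beforehand and any check of gene length, GC content or position were not analysed here. Alternatives were a threshold of 0.01, a fold change of at least 1.5, an absolute log2 fold change of at least 1, a mean of at least 50, and no filter on low means. The authors' adjusted p-value, which was the test planned at first, became an alternative after the data had been seen. Fold over standard error rescaled to its spread across genes was added after the data had been seen.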

Results

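ADAR3 is a brain-enriched member of the ADAR family of double-stranded RNA-binding proteins that lacks detectable deaminase activity, and its arginine-rich R-domain can bind single-stranded RNA. The study asked how the R-domain contributes to the RNAs that ADAR3 associates with across the transcriptome. FLAG-tagged ADAR3 WT, the R-mutant, or an empty vector was expressed in U373-MG glioblastoma cells, and RNA from FLAG immunoprecipitates (IP) was sequenced beside input RNA. There were 3 libraries in each of the 6 groups formed by genotype and fraction. IP enrichment is given throughout as the log2 ratio of IP over input in one genotype to IP over input in another, as read from the authors' deposited tables. The median of the mean normalized count among tested genes lay between 143 and 315 in the 4 tables. The median standard error for genes with a mean of at least 50 lay between 0.22 and 0.28 on the log2 scale. Genes are given by Ensembl ID because the tables carry no symbols. Fold changes and standard errors beside an ID are those of the authors' deposited tables, while adjusted p-values marked as from the normal test were computed here.

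Expression of ADAR3 WT was accompanied by a broad change in the RNAs recovered in the FLAG IP relative to the empty vector. Of 21121 genes tested, 1266 had higher and 1720 had lower IP enrichment in ADAR3 WT than in control (normal test of fold over standard error, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 1.01 among the higher genes and -1.03 among the lower genes. At least a 2-fold difference was reached by 641 of the higher and 917 of the lower genes. Counts were normalized between libraries, so higher and lower in all IP comparisons are relative to the other RNAs. A gain of some RNAs in the IP can lower the values of the rest. Lower enrichment therefore does not by itself show that ADAR3 excluded an RNA. Among IDs with a mean of at least 50, the largest rise in the authors' deposited table was that of ENSG00000198695, at a log2 fold change of 4.85 ± 0.24 (standard error), or 28.8-fold (normal test adjusted p 1.28e-86). It was followed by ENSG00000210127 at 3.04 ± 0.41 in the authors' deposited table (normal test adjusted p 4.07e-11). The largest falls in the authors' deposited table were those of ENSG00000226782 at -5.20 ± 0.46 (normal test adjusted p 3.89e-26) and ENSG00000276168 at -5.13 ± 1.39 (normal test adjusted p 0.00333). The mean normalized count of ENSG00000226782 was 235 in this comparison, but 29.4 in R-mutant over ADAR3 WT and 21.5 in input. Its fall thus appears to rest largely on signal in the control IP libraries.

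The 2 directions were not spread alike over mean normalized count. That mean is over the libraries of the authors' model and may include IP signal, so it does not measure expression alone. Genes were divided into 5 groups of equal size by mean normalized count. In the lowest group, 0.97% had higher and 0.426% had lower enrichment in ADAR3 WT. In the middle group, with a median mean of 235, the shares were 9.54% and 7.60%. In the highest group, with a median mean of 3347, 8.24% were higher and 14.9% were lower, and in the next highest group the shares were 8.29% and 15.9%. The median log2 fold change of all genes moved the same way, from 0.31, 0.16 and 0.03 in the lower 3 groups to -0.11 and -0.05 in the highest ones. The power to call a gene also rose with the mean, so the low shares in the lowest group give no measure of how many low-count RNAs changed. With the authors' adjusted p in place of the test of the fold change, 9080 genes passed in the authors' deposited table, 4067 higher and 5013 lower, of which 2921 were among the 2986 genes called here.

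**Figure D1:**
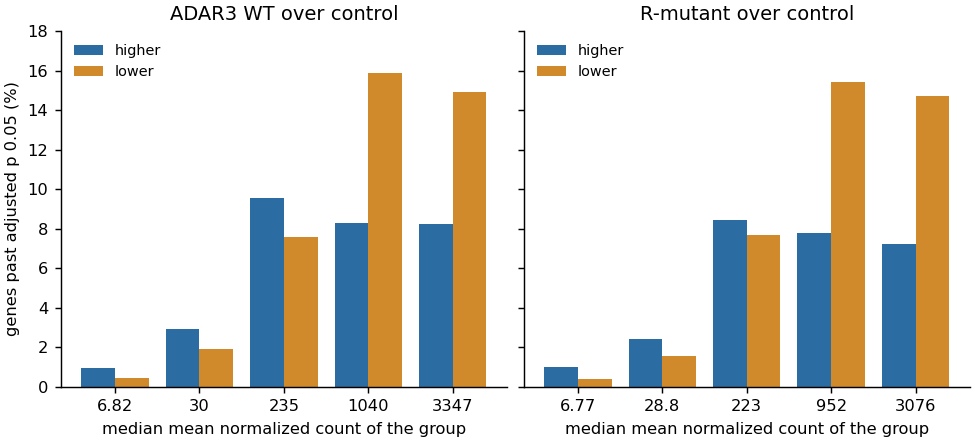
Share of tested genes (percent, vertical axis) with higher (blue) or lower (orange) IP enrichment at an adjusted p under 0.05, in 5 groups of genes of equal size ordered by mean normalized count (horizontal axis, median of each group), for ADAR3 WT over control and R-mutant over control. In the highest group for ADAR3 WT, 8.24% of genes were higher and 14.9% were lower.

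The R-mutant gave a change of similar extent against the same control. Of 21120 genes tested, 1136 had higher and 1678 had lower IP enrichment in the R-mutant than in control, with median log2 fold changes of 1.03 and -1.11. At least a 2-fold difference was reached by 589 higher and 1043 lower genes. ENSG00000198695 again had the largest rise among IDs with a mean of at least 50, at 4.80 ± 0.24 in the authors' deposited table (normal test adjusted p 7.25e-87), followed by ENSG00000210135 at 3.46 ± 0.59 (normal test adjusted p 4.27e-07). The largest falls in the authors' deposited table were those of ENSG00000240869 at -4.42 ± 0.50 (normal test adjusted p 4.21e-16) and ENSG00000259001 at -4.23 ± 0.32 (normal test adjusted p 7.59e-35). As with ADAR3 WT, lower calls outnumbered higher calls in the highest of the 5 groups by mean count, at 14.7% against 7.24%, and the median log2 fold change of all genes moved from 0.42 in the lowest group to -0.04 in the highest. By the authors' adjusted p, 8626 genes passed in the authors' deposited table, 3768 higher and 4858 lower.

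The genes enriched with ADAR3 WT and with the R-mutant were largely shared. Among 20855 genes tested in both comparisons, 991 were higher in both, which is 78.3% of the 1266 called for ADAR3 WT and 87.5% of the 1132 called for the R-mutant. Another 1466 genes were lower in both, out of 1720 and 1678. Independent lists of these sizes would share 68.7 higher and 138 lower genes. No gene was called in opposite directions. Both comparisons use the same control libraries. At an unadjusted p under 0.05 in both, 4469 of 20804 genes tested in all 3 IP comparisons had fold changes of the same sign, where simulations of shared controls without effects gave an average of 344.

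Across 20804 genes tested in all 3 IP comparisons, the fold changes of ADAR3 WT and R-mutant against control had a Pearson r of 0.895, where shared controls alone gave a simulated r of 0.709. Across the 13431 genes with a mean of at least 50, r was 0.971, against a simulated r of 0.686. The covariance of the fold changes in these genes was 0.427, against 0.0706 from shared controls alone, a difference of 0.356. Part of the overlap of calls and of these correlations may still come from the shared controls. The control libraries were not split, and the simulations hold no error common to all of them.

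**Figure D2:**
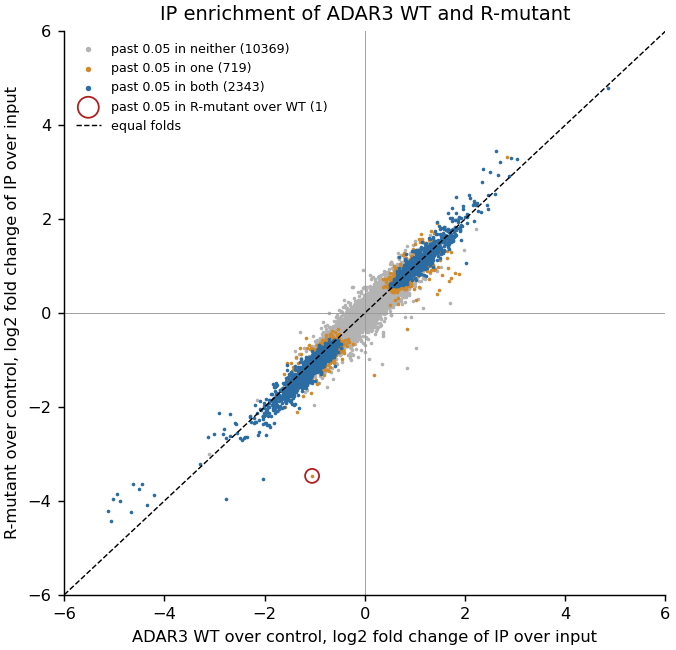
IP enrichment over control of ADAR3 WT (horizontal axis) and of the R-mutant (vertical axis), both as log2 fold changes, for the 13431 genes with a mean of at least 50 in each IP table. Points are coloured by whether the adjusted p was under 0.05 in neither, in 1 or in both comparisons, the dashed line marks equal fold changes, and the ringed gene is ENSG00000202198, the 1 gene called in R-mutant over ADAR3 WT.

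The direct comparison of R-mutant with ADAR3 WT asks which RNAs differ in IP enrichment relative to the other RNAs. Counts were normalized between libraries, so a loss of RNA binding that is alike for all genes would not appear in it. Of 23385 genes tested, 0 had higher and 1 had lower IP enrichment in the R-mutant than in ADAR3 WT (normal test of fold over standard error, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 there were 146 genes, 56 higher and 90 lower, or 0.624% of those tested. This share lies far under the nominal 0.05 that well-sized standard errors would give without any difference. The standard errors were thus wide for this test, and its calls were conservative. The called gene, ENSG00000202198, had a log2 fold change of -2.41 ± 0.44 in the authors' deposited table (normal test adjusted p 0.00111). The 95% interval of the fold change excluded a 2-fold difference in either direction for 12915 genes, 55.2% of those tested. For the remaining genes a difference of that size was not excluded.

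The number of genes in this comparison depended strongly on the test. By the authors' adjusted p, 11947 genes passed in the authors' deposited table, 5034 higher and 6913 lower. Their median absolute log2 fold change was 0.10, and in 10589 of them (88.6%) the fold change was smaller than its own standard error. Across genes, the authors' statistic had a rank correlation of -0.00518 with the size of the fold change over its standard error, against 0.606 for ADAR3 WT over control. Fold over standard error had a standard deviation of 0.659 across genes. When it was rescaled to its robust spread of 0.605, 78 genes passed, 33 higher and 45 lower, a test added after the data had been seen.

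**Figure D3:**
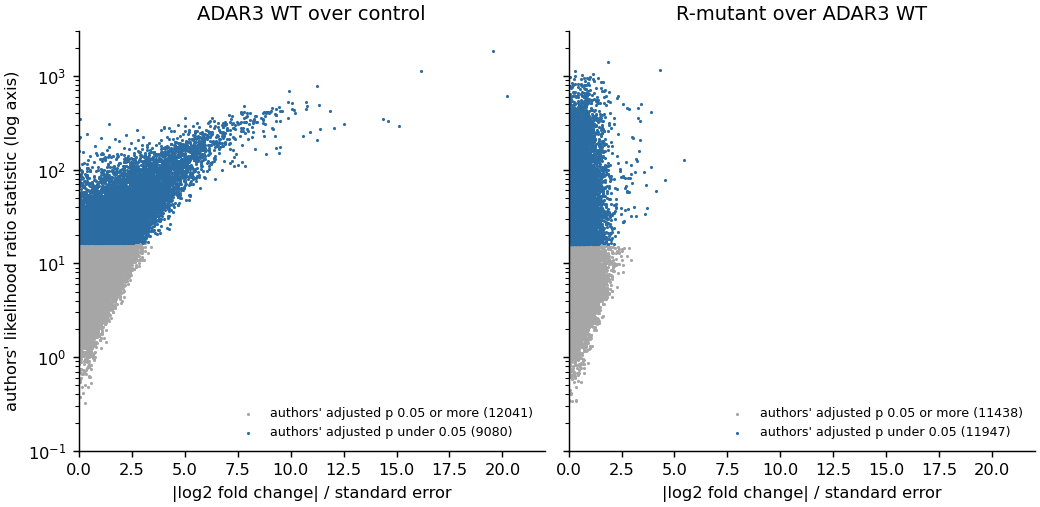
The authors' likelihood ratio statistic (vertical log axis) against the absolute log2 fold change divided by its standard error (horizontal axis), 1 point per tested gene, for ADAR3 WT over control and for R-mutant over ADAR3 WT. Blue points have an authors' adjusted p under 0.05, which were 9080 and 11947 genes. In the second panel they reach from the top to the threshold at fold changes near 0. Statistics under the lower end of the vertical axis are drawn at that end.

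Genes enriched with ADAR3 WT were examined for loss of enrichment in the R-mutant. None of the 1266 genes was called in R-mutant over ADAR3 WT (normal test, adjusted p under 0.05), and 25 had an unadjusted p under 0.05, 21 of them lower in the R-mutant. Their median log2 fold change of R-mutant over ADAR3 WT was -0.03, and 784 of them (61.9%) lay below 0. Part of this is a general offset, since the median of all tested genes was -0.02. Relative to that median, theirs was -0.0164, and 55.2% of them lay lower. The 95% interval excluded a 2-fold difference for 1118 of them (88.3%). Both comparisons use the ADAR3 WT libraries, which biases these genes downward. With equal true enrichment in both genotypes and no general offset, simulation gave a median of -0.06 with 60.3% below 0 at the deposited standard errors. At errors scaled to the spread of R-mutant over ADAR3 WT it gave -0.03 with 57.2% below 0. The observed shift relative to all tested genes was no larger than in either simulation. Of 4067 genes enriched by the authors' adjusted p, 2028 passed it in R-mutant over ADAR3 WT with a fold change below 0, and 1812 with one above 0. That test covers more terms than this fold change, so these counts do not measure loss or gain of enrichment.

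In the input RNA, few genes passed the test between ADAR3 WT and control. Of 20411 genes tested, 21 were higher and 38 were lower in ADAR3 WT input than in control input (normal test of fold over standard error, Benjamini-Hochberg adjusted p under 0.05), and the authors' adjusted p gave the same counts. The middle part of the log2 fold changes of the higher genes ran from a lower quartile of 1.02 to an upper quartile of 1.76, and that of the lower genes from -1.41 to -1.01. The largest rise in the authors' deposited table, ENSG00000185736 at 10.09 ± 0.34 (normal test adjusted p 7.88e-186), stood far above the next, ENSG00000165323 at 2.04 ± 0.31 (normal test adjusted p 2.16e-07). The largest falls in the authors' deposited table were those of ENSG00000236719 at -2.12 ± 0.37 and ENSG00000077264 at -2.11 ± 0.37, both with a normal test adjusted p of 2.19e-05. In input, 595 genes (2.92%) had an unadjusted p under 0.05 by the normal test, a share also under the nominal 0.05. With fold over standard error centred and rescaled to its spread across genes, added after the data had been seen, 489 genes passed, 123 higher and 366 lower.

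IP enrichment followed input change only weakly. Across 20129 genes, the Spearman correlation of IP enrichment in ADAR3 WT over control with the input fold change was -0.124, and over the 13411 genes with a mean of at least 50 in both it was -0.0188. Input libraries enter both values, which gives a negative correlation by chance. Of the 21 genes higher in input, 1 was higher and 2 were lower in IP enrichment of ADAR3 WT over control, and of the 38 lower in input, 4 were higher and 0 were lower by the same test. ENSG00000185736, the gene with the largest rise in input, had in the authors' deposited tables an IP enrichment of -3.01 ± 0.75 in ADAR3 WT over control (normal test adjusted p 0.00106). It was -2.58 ± 0.79 in R-mutant over control (normal test adjusted p 0.0129). Its rise in input was 1093-fold on a mean of 16540, so control input held few counts of it. Both IP values against control rest on these few counts and may not reflect depletion of ENSG00000185736. In R-mutant over ADAR3 WT its log2 fold change was 0.41 ± 0.27 in the authors' deposited table, which did not pass.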

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

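The test of the fold change used here was chosen after the data had been seen. The only gene whose IP enrichment differed between ADAR3 WT and the R-mutant by the direct test was ENSG00000202198, with a log2 fold change of -2.41 ± 0.44 for R-mutant over ADAR3 WT in the authors' deposited table (normal test adjusted p 0.00111). In that table its mean normalized count was 113. In the authors' deposited tables its enrichment was -3.47 ± 0.54 in R-mutant over control (normal test adjusted p 1.79e-08) and -1.05 ± 0.54 in ADAR3 WT over control (normal test adjusted p 0.199). The adjusted p of the likelihood ratio test in the authors' deposited tables was 4.28e-23, 1.26e-12 and 0.0331 for these 3 comparisons in the same order. Its input fold change for ADAR3 WT over control was -0.14 ± 0.42 in the authors' deposited table. The difference was not weighed further, because values per library were not analysed here.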

How the results depend on the processing

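No paired analysis was possible because the deposited comparison tables give no per-library values that match the labels. For that reason the fits planned with other count models, other size factors, a replicate left out, a replicate block or only the compared genotypes were not run, nor were other splits of the samples. The planned gene list alternatives were not run because IDs could not be paired with symbols. The rescaled statistic and the correlation between ADAR3 WT and R-mutant at a mean of at least 50 were chosen after the data had been seen. The authors' adjusted p was the planned test, and the normal test of the fold change replaced it after the data had been seen. At an adjusted p under 0.01, by construction stricter, the counts were 1823 for ADAR3 WT over control, 1681 for R-mutant over control and 37 for input, with 529 genes higher in both genotypes. With an absolute log2 fold change of at least 1 they were 1558 and 1632, with 473 higher in both. By the authors' adjusted p they were 9080 and 8626, with 3265 higher in both, and 11947 for R-mutant over ADAR3 WT. Of the genes enriched with ADAR3 WT by that test, 2028 passed it in R-mutant over ADAR3 WT with a negative fold change. That test does not measure the fold change alone. With a mean of at least 50, R-mutant over ADAR3 WT had 2 genes, adding ENSG00000263934 (-1.52 ± 0.33 in the authors' deposited table; normal test adjusted p 0.0344, and 0.0583 over all tested genes), named after its value was seen. Rescaling gave 78 genes there and 489 in input. At a mean of at least 50, the correlation of IP enrichment with input change was -0.0188 and that between ADAR3 WT and R-mutant was 0.971; the cause of these moves was not tested. Other counts lay within 1.5 times those reported, at 2457 to 3125, 2315 to 2975 and 44 to 59 genes. The 12 IDs chosen as highest or lowest kept their calls in all 79 combinations of ID and setting tried, each in the comparison it was chosen in. Because they were chosen as the largest called folds with a mean of at least 50, the fold and mean settings could hardly drop them. Depth per library is unknown, and a log2 change of 1 was recovered in 24.5% to 42.0% of simulated genes, and in 37.7% to 66.4% of those with a mean of at least 50.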

Other observations

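All tests of explanations in this part were chosen after related results had been seen. Intervals on medians and on observed slopes here come from resampling genes, so they hold no variation between libraries. Among 13431 genes with a mean of at least 50, R-mutant over ADAR3 WT varied with how far a gene lay from the control. In the 989 genes whose mean log2 enrichment over control, averaged over both genotypes, was below -1, the median of R-mutant over ADAR3 WT was -0.11 (95% interval -0.12 to -0.10), and 76.6% lay below 0, against 57.5% of all 13431 genes. Relative to the median of all of these genes, -0.02, 71.3% lay lower, so part of the excess is a general offset. In the 628 genes above 1 the median was -0.01 (-0.03 to -0.0037). Among genes lower in both comparisons against control, 1120 of 1466 (76.4%) lay below 0, against 520 of 991 (52.5%) of those higher in both.

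For the slightly stronger depletion in the R-mutant, the slope of R-mutant over ADAR3 WT on the mean enrichment was 0.0423 (95% interval 0.0220 to 0.0614) for genes below 0, where simulated errors alone gave 0.00932 (-0.00935 to 0.0269), a range that overlaps it. A difference in IP yield that scales the log2 enrichment of all genes alike would give a slope above 0 on both sides. For genes above 0 the slope was 0.00515 (-0.00743 to 0.0188), and errors alone gave 0.0127 (-0.00443 to 0.0317). This argues against such uniform scaling as the whole cause. Carry-over of unbound RNA need not scale all genes alike and could act mostly on depleted genes, so these slopes do not test it. Larger independent errors in the R-mutant would not pull down genes chosen without its libraries, yet the 1720 genes lower in ADAR3 WT over control had a median of -0.06, which was -0.0458 (-0.0544 to -0.0358) relative to all tested genes, where equal true effects gave a simulated median of 0.06 at the deposited standard errors and 0.02 at scaled ones. Among genes of like mean count (50 bins) the slope was 0.0428 (0.0233 to 0.0629), and it was 0.0327 (-0.00609 to 0.0800), 0.0516 (0.0230 to 0.0754) and 0.0461 (0.0177 to 0.0758) in 3 groups of rising mean, which argues against a trend with mean count as the whole cause. Errors shared by many genes in the R-mutant libraries, and a weaker association of these RNAs with the R-mutant, were not tested.

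The gap between 11947 genes past the authors' adjusted p and 1 past the test of the fold change in R-mutant over ADAR3 WT is consistent with the authors' statistic covering terms other than the printed fold change. That statistic had a rank correlation of -0.00518 with the size of fold over standard error in this comparison. Standard errors were also wider than the spread of the fold changes, since fold over standard error had a standard deviation of 0.659 across genes. Such errors could hide real differences. The fold changes of the authors' calls were 1.202 times those of uncalled genes of like mean count, against 2.58 times in ADAR3 WT over control. This leaves open whether real differences were hidden.

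The likeness of ADAR3 WT and R-mutant enrichment against control is more than the noise of the shared control libraries that the standard errors describe. The covariance exceeded the one simulated from that noise by 0.356. An error common to all control libraries would enter both comparisons and was not simulated. Over the 2980 genes called for ADAR3 WT, the Spearman correlation of input change with IP enrichment was -0.123, so these fold changes followed input change only weakly. Shared input libraries push this value below 0, and R-mutant input was not compared here. Input expression carried into both comparisons was therefore not tested. A biological reading, in which these associations do not need the R-domain, was not tested apart from the direct comparison. There, the 95% interval excluded a 2-fold difference for 88.3% of the genes enriched with ADAR3 WT. That comparison cannot show a change in RNA binding that is alike for all genes. Any FLAG-tagged protein could shift RNA recovery from that of an empty vector, and an IP of an unrelated tagged protein was not analysed here.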
